A study of Mus musculus with 6 samples.

How the data were processed

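Polyadenylated RNA of 6 libraries, 3 control (floxed Myc) and 3 Myc-deleted, was sequenced from stranded mRNA preparations, per the labels. The values are RSEM expected counts per gene, deposited by the authors with no scaling between libraries. Their processing notes name cutadapt, STAR, Picard and RSEM and the mouse build mm10. Tool versions and the annotation release are not given in the sources used here. The extraction protocol names liver and the other labels name intestine.

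The table held 47643 genes, of which 99.1% were matched by Ensembl identifier to a symbol in GENCODE M21 (GRCm38), 82.1% with the same identifier version. 24952 genes were at 0 in all libraries. Library totals ranged from 9956938 to 11328693, and 3 counts corresponded to 0.265 to 0.301 CPM. The precision of a single count covers counting error only.

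Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the edgeR quasi-likelihood F-test of Myc-deleted over control, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are on the log2 scale with SE, and levels are TMM-scaled CPM with SD. The SE was the absolute log2 fold change over the square root of the F statistic, so it includes variation between libraries. Log2 CPM used a prior count of 2. The level of Myc was compared by a two-sided exact permutation test.

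The 48 gene lists were fixed before the data were examined, and the 44 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Member counts are given over all genes and adjusted over the list alone. In list results, risers and fallers are members past the threshold. The genes named were 14 chosen in advance, the 8 with the largest change in each direction among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups, up to 4 members with the lowest p of each list with a call, and up to 3 abundant members of lists that stood apart. Among the members this rule allowed, those that kept their call when a library was left out were preferred, a choice made after the values were seen. Rps27l, Fabp6, Myh11, Alb and the neighbours of Myc other than Pvt1 and Gsdmc3 were also named after their values were seen. Results for some genes are not reported.

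Alternatives were RLE and upper-quartile scaling, DESeq2, limma voom, 2 other filters on low counts, the replicate number as a block, each library left out in turn, glmTreat against a 1.2-fold change, an adjusted p of 0.1, and for the lists an estimated correlation, ranks and fry. TMM factors without the ribosomal protein and interferon genes were added after seeing the data. The procedure was tested on simulated data with 50 changed genes at each of 4 fold changes. It recovered 2.00% of those changed 1.25-fold, 44.0% at 1.5-fold, 72.0% at 2-fold and 92.0% at 4-fold, and 14 of 119 calls were false (11.8%, above the nominal 5%).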

Results

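Messenger RNA of the intestine was sequenced from 6 male C57BL/6 mice, 7 to 8 weeks old, that had received tamoxifen and a 60% high-fat diet for 2 weeks. In 3 of them the labels give a tamoxifen-inducible deletion of Myc in the intestinal epithelium (Myc-deleted), and the other 3 carried the floxed gene (control). Myc encodes a transcription factor that drives cell growth and ribosome production. Control libraries 1 to 3 held 10075957, 11328693 and 9956938 expected counts and Myc-deleted libraries 1 to 3 held 11157715, 10636658 and 10894123. The labels name the intestine without a segment, while the extraction protocol names liver. Fabp6, the ileal bile acid binding protein, stood at 11004 ± 1462 CPM (normalised counts; SD, n = 3) in the controls and 10559 ± 951 CPM in the Myc-deleted mice. Alb, which hepatocytes secrete in bulk, stood at 2.61 ± 0.667 and 0.582 ± 0.433 CPM.

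The comparison asked how the intestinal transcriptome of mice on a high-fat diet differs when Myc is deleted. The labels do not say whether the controls carry a Cre recombinase. For every difference below, loss of Myc and activity of a recombinase therefore cannot be told apart. Myc itself (ENSMUSG00000022346.14, chromosome 15, 61985391 to 61990374, GRCm38) was measured at 5.98 ± 0.102 CPM in the controls and 4.49 ± 1.26 CPM in the Myc-deleted mice (SD, n = 3 each). Its counts were 59, 70 and 59 in control libraries 1 to 3 and 36, 47 and 63 in Myc-deleted libraries 1 to 3. The difference did not pass the test (log2 fold change -0.41 ± 0.22 SE, edgeR adjusted p = 0.318), nor in any leave-one-out run (adjusted p = 0.141 to 0.580). The log2 fold change was -0.23 without Myc-deleted library 1 and -0.65 without Myc-deleted library 3. A two-sided exact permutation test of log2 CPM gave p = 0.1, the smallest that 3 against 3 can give. Myc-deleted library 3 stood at 5.81 CPM, against 5.86 to 6.05 CPM in the controls, so the level of Myc does not check its label. Gene-level counts do not show which exons the reads cover.

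In the Myc-deleted mice, mRNAs of the cytosolic ribosome were lower almost throughout, with 73 of 80 ribosomal protein genes lower and a median log2 fold change of -0.63. Of the genes that rose, 24 were among 43 interferon-response genes, 9 among 24 p53 targets, 6 among 22 crypt stem cell markers and 4 among 21 enteroendocrine markers. The camera set test with an estimated correlation called none of these lists (adjusted p = 0.377 for the ribosomal proteins, 0.102 for the p53 targets and 0.449 for each of the other 3). The fry set test called the ribosomal proteins (fry adjusted p = 0.0265) and the p53 targets (0.000139). Fry did not call the interferon (fry adjusted p = 0.115), stem cell (0.0563) or enteroendocrine list (0.0501). Leaving out 1 library gave 8 to 25 interferon-response and 2 to 5 enteroendocrine risers. Fgf15, the ileal hormone that represses bile acid synthesis, rose 3.86-fold, and Gcg, the gene of glucagon-like peptide 1, rose 1.96-fold. The secreted defence gene Reg3b fell, 4.07-fold lower. By the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment, 537 of 12720 genes were higher and 474 lower, and 172 and 77 of these differed at least 2-fold.

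**Figure D1:**
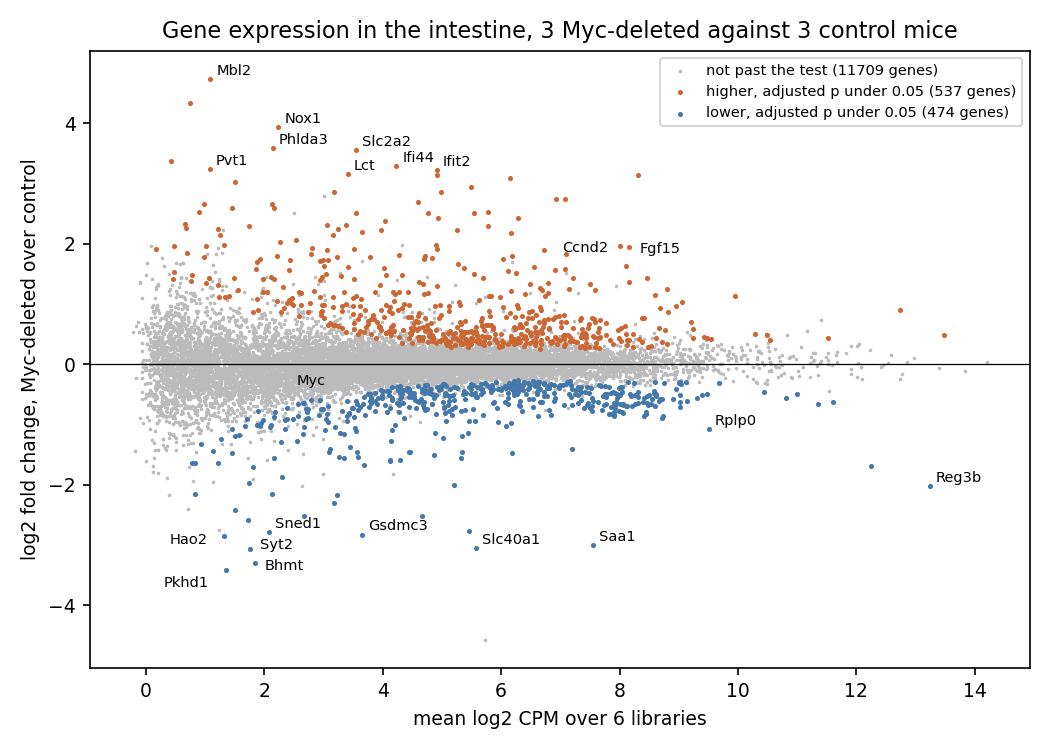
Each point is 1 of the 12720 tested genes, with its mean log2 CPM over the 6 libraries on the horizontal axis and its log2 fold change, Myc-deleted over control, on the vertical axis. The 537 higher genes are orange, the 474 lower genes blue and the rest grey, with Myc among the grey points at -0.41.

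The largest rises among the named genes were those of Mbl2, a mannose-binding lectin (log2 fold change 4.74 ± 0.53 SE), Nox1, an epithelial NADPH oxidase (3.94 ± 0.78), and Phlda3, a p53 target (3.59 ± 0.40). They were followed by Slc2a2, the glucose transporter GLUT2 (3.56 ± 0.24), Ifi44 (3.29 ± 0.70), Pvt1 (3.25 ± 0.51), Ifit2 (3.22 ± 0.81) and Lct, which encodes lactase (3.15 ± 0.57). Counts were 0, 3 and 1 for Mbl2 in control libraries 1 to 3, 2 and 2 for Pvt1 in control libraries 1 and 2, 1 for Nox1 in control library 3 and 2 for Phlda3 in control library 1. Pkhd1 had 3 counts in Myc-deleted library 2 and 3 in library 3, and Syt2 had 3 in library 1 and 3 in library 3, so the folds of these 6 genes are imprecise. Pvt1, a long noncoding RNA gene next to Myc (chromosome 15, 62037986 to 62378096), reached 3.44 ± 1.27 CPM in the Myc-deleted mice. The largest falls were those of Pkhd1 (-3.42 ± 0.41), Bhmt, a methyltransferase of the methionine cycle (-3.30 ± 0.43), Syt2 (-3.07 ± 0.52) and Slc40a1, the iron exporter ferroportin (-3.05 ± 0.26). Saa1 (8.00-fold lower), Hao2 (-2.85 ± 0.37), Gsdmc3 (-2.83 ± 0.41) and Sned1 (-2.79 ± 0.29) came next. Nox1, Ifi44, Ifit2 and Lct did not pass with limma voom (adjusted p = 0.0911, 0.103, 0.185 and 0.0642). Without control library 2 the edgeR adjusted p was 0.0606 for Nox1, 0.0986 for Ifi44, 0.161 for Ifit2 and 0.0546 for Lct. Without control library 3 it was 0.0541 for Nox1, 0.0729 for Ifi44 and 0.0956 for Ifit2, which had 0.110 without control library 1. Without Myc-deleted library 3 the log2 fold changes of Ifi44 and Ifit2 were 2.10 and 1.504.

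Among the cytosolic ribosomal proteins, 73 of 80 genes fell and 1 rose (1 higher and 77 lower adjusted over the list alone). Rplp0 went from 987 ± 71.3 to 469 ± 27.4 CPM (-1.07 ± 0.09, adjusted p = 0.000361), and Rps18 (-0.81 ± 0.08) also fell. Rps27l, a p53 target that resembles Rps27, was the riser (0.38 ± 0.08) and is named after its values were seen. Its adjusted p was 0.0586 to 0.0799 without control library 1, 2 or 3 or Myc-deleted library 2 or 3, so that 0 rose in those runs. The camera set test called the list lower (camera adjusted p = 1.46e-81, and adjusted p = 0.377 with an estimated correlation). Of 63 translation initiation and elongation factors, 13 fell and 2 rose (2 higher and 14 lower adjusted over the list alone; camera adjusted p = 0.0170, and adjusted p = 0.617 with an estimated correlation), with Eef1b2 (-0.77 ± 0.09), Eif3f (-0.55 ± 0.08) and Eef2 (-0.56 ± 0.08) among the fallers. For translation initiation and elongation factors, risers numbered 0 without control library 2 and 1 without control library 3 or Myc-deleted library 3, fallers numbered 7 without control library 1 and 6 without control library 2, and the camera adjusted p was 0.140 without Myc-deleted library 1. Of 71 ribosome biogenesis genes, 4 fell and 1 rose (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0168, and adjusted p = 0.617 with an estimated correlation). Npm1, a nucleolar chaperone (-0.51 ± 0.09), and Tsr1 (-0.61 ± 0.11) fell, and Ltv1 rose (0.57 ± 0.10). For ribosome biogenesis, fallers numbered 2 in each leave-one-out run, and the camera adjusted p was 0.214 without Myc-deleted library 1. Among 22 cytosolic tRNA synthetases the median was -0.14 (-0.23 without Myc-deleted library 3) and no gene passed (camera adjusted p = 0.0461, and adjusted p = 0.676 with an estimated correlation). For cytosolic tRNA synthetases, the camera adjusted p was 0.0962 without control library 2, 0.0891 without control library 3, 0.353 without Myc-deleted library 1 and 0.0737 without Myc-deleted library 2.

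Of 38 canonical Myc targets, 2 rose and 3 fell (2 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.177). The cyclin gene Ccnd2 went from 105 ± 13.2 to 409.9 ± 43.2 CPM (1.97 ± 0.11, adjusted p = 7.27e-05). Odc1, the rate-limiting enzyme of polyamine synthesis, rose (0.70 ± 0.10, adjusted p = 0.00291), and Tfrc, the transferrin receptor, fell (-1.15 ± 0.15, adjusted p = 0.00231). Ncl (-0.28 ± 0.11, adjusted p = 0.156, and a fold change of -0.18 without Myc-deleted library 1) and Ldha (0.01 ± 0.08, adjusted p = 0.948) did not pass. The sign of Ldha turned with upper-quartile scaling (-0.03), without control library 2 (-0.00519) and without Myc-deleted library 3 (-0.01). In the Myc network of 13 genes the median was -0.13 and no gene passed (camera adjusted p = 0.186). Of these genes 10 had a negative and 3 a positive fold change, and the fry set test called the list lower (fry adjusted p = 0.0326). Of 56 cell cycle genes, Ccnd2 rose (1 higher adjusted over the list alone; camera adjusted p = 0.625). Mki67, a marker of proliferating cells, did not pass (-0.39 ± 0.12, adjusted p = 0.0826), but did so without a filter on low counts (adjusted p = 0.0389) and with the replicate number as a block (0.0282).

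Of 24 p53 targets and apoptosis genes, 9 rose and 1 fell (10 higher and 2 lower adjusted over the list alone; camera adjusted p = 7.57e-09, and adjusted p = 0.102 with an estimated correlation). Ccng1 had the smallest adjusted p of all genes, with 46.1 ± 1.84 CPM in the controls and 141 ± 2.05 CPM in the Myc-deleted mice (3.05-fold, adjusted p = 1.40e-05). Phlda3 and the death receptor gene Tnfrsf10b (1.11 ± 0.13) rose, and the stress-response gene Sesn1 fell (-0.57 ± 0.08). The mean log2 CPM of the list was 4.40 ± 0.0431 in the controls and 4.84 ± 0.00111 in the Myc-deleted libraries.

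**Figure D2:**
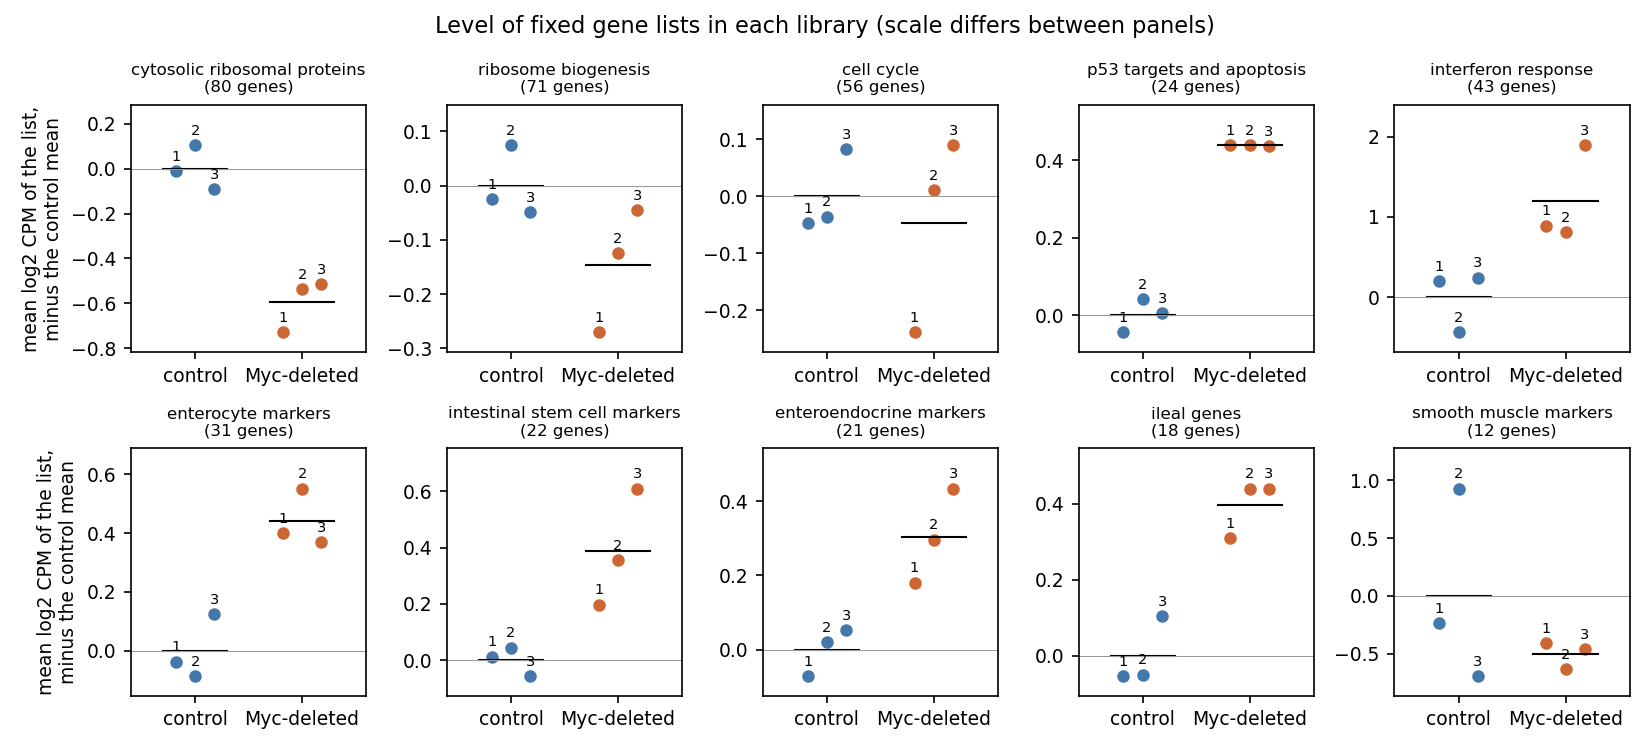
Mean log2 CPM of 10 fixed gene lists in each library, as the difference from the control mean, with library numbers beside the points, group means as black bars and a separate scale per panel. The ribosomal protein list differed by -0.59 and the p53 list by 0.44, and control library 2 stands apart in the smooth muscle panel.

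Of 22 intestinal stem cell markers, 6 rose (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.25e-05, and adjusted p = 0.449 with an estimated correlation), including Igfbp4 (1.48 ± 0.18), Cd44 (1.32 ± 0.16), Rnf43 (0.82 ± 0.11) and Ephb2 (0.96 ± 0.15). For intestinal stem cell markers, fallers numbered 1 without Myc-deleted library 3. Olfm4, another stem cell marker, stood at 6.02 ± 0.389 CPM in the controls and 3.13 ± 1.37 CPM in the Myc-deleted mice. It was lower in each of these than in any control, where 27.8% of all tested genes had groups that did not overlap. Olfm4 did not pass (-0.94 ± 0.28, adjusted p = 0.0738). It passed with limma voom (adjusted p = 0.0473), without a filter on low counts (0.0252) and without Myc-deleted library 3 (0.0108). Lgr5 had 4 to 10 counts per library and was not tested. Of 21 enteroendocrine markers, 4 rose (5 higher adjusted over the list alone; camera adjusted p = 0.00150, and adjusted p = 0.449 with an estimated correlation), including Gcg (0.97 ± 0.13, adjusted p = 0.00243) and the somatostatin gene Sst (0.78 ± 0.12). For enteroendocrine markers, risers numbered 2 without control library 1 or 2 or Myc-deleted library 2 or 3. Of 31 enterocyte markers, 7 rose (8 higher adjusted over the list alone; camera adjusted p = 1.22e-05, and adjusted p = 0.449 with an estimated correlation), led by Slc2a2, which went from 1.75 ± 0.851 to 20.99 ± 0.359 CPM. For enterocyte markers, risers numbered 1 without control library 2, 4 without control library 3 and 3 without Myc-deleted library 2. The mean log2 CPM of the enterocyte list differed by 0.440 between the groups. Without the 9 of 31 genes that another list holds, Slc2a2, Lct and Fabp2 among them, it differed by 0.133 (Myc-deleted SD 0.120). No gene passed among 21 Paneth cell markers (median 0.26; camera adjusted p = 0.0207, and adjusted p = 0.676 with an estimated correlation), 22 goblet cell markers (median 0.06; camera adjusted p = 0.182) or 18 tuft cell markers (median -0.13; camera adjusted p = 0.399). For Paneth cell markers, risers numbered 3 without Myc-deleted library 1 and 1 without Myc-deleted library 3, and the camera adjusted p was 0.449 without control library 3, 0.0581 without Myc-deleted library 2 and 0.208 without Myc-deleted library 3. For goblet cell markers, risers numbered 2 without Myc-deleted library 1. Lyz1, the Paneth cell lysozyme (0.31 ± 0.22, adjusted p = 0.463), and Muc2, the goblet cell mucin (0.19 ± 0.10, adjusted p = 0.307), did not pass. The log2 fold change of Lyz1 was 0.49 without control library 1, 0.08 without control library 3, 0.47 without Myc-deleted library 1 and 0.16 without Myc-deleted library 3, and the Paneth median was 0.08 without control library 3, 0.43 without Myc-deleted library 1 and 0.13 without Myc-deleted library 3.

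Of 12 bile acid transport and Fxr target genes, 4 rose and 1 fell (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.161), with a median of -0.05, a mean of 0.36 and a test in the upward direction. For bile acid transport and Fxr targets, fallers numbered 2 without Myc-deleted library 1. Fgf15 (chromosome 7, 144896531 to 144900953) went from 117 ± 35.8 to 453 ± 141 CPM (1.95 ± 0.26, adjusted p = 0.00236). Nr0b2, which encodes the nuclear receptor SHP, rose (2.59 ± 0.31, adjusted p = 0.00149), as did the exporter gene Abcc2 (0.60 ± 0.11), and the vitamin D receptor gene Vdr fell (-0.46 ± 0.09). Of 18 ileal genes, 5 rose (7 higher adjusted over the list alone; camera adjusted p = 6.71e-05, and adjusted p = 0.276 with an estimated correlation), Tm4sf5 (1.23 ± 0.16), Fgf15 and Gcg among them. Fabp6 did not pass (-0.06 ± 0.14, adjusted p = 0.846), and its sign turned without control library 1 (0.04). Of 14 proximal small intestine genes, 4 rose and 1 fell (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.186). For proximal small intestine genes, risers numbered 2 without control library 2. Slc40a1 was the faller, and Gsta1 (1.23 ± 0.22) and the transcription factor gene Gata4 (1.496 ± 0.27) were among the risers. Of 7 colonic genes, 3 fell (3 lower adjusted over the list alone; camera adjusted p = 0.000200, and adjusted p = 0.377 with an estimated correlation), led by the carbonic anhydrase gene Car4 (-1.41 ± 0.14, adjusted p = 0.000850) and Saa1. For colonic genes, risers numbered 1 without Myc-deleted library 1.

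**Figure D3:**
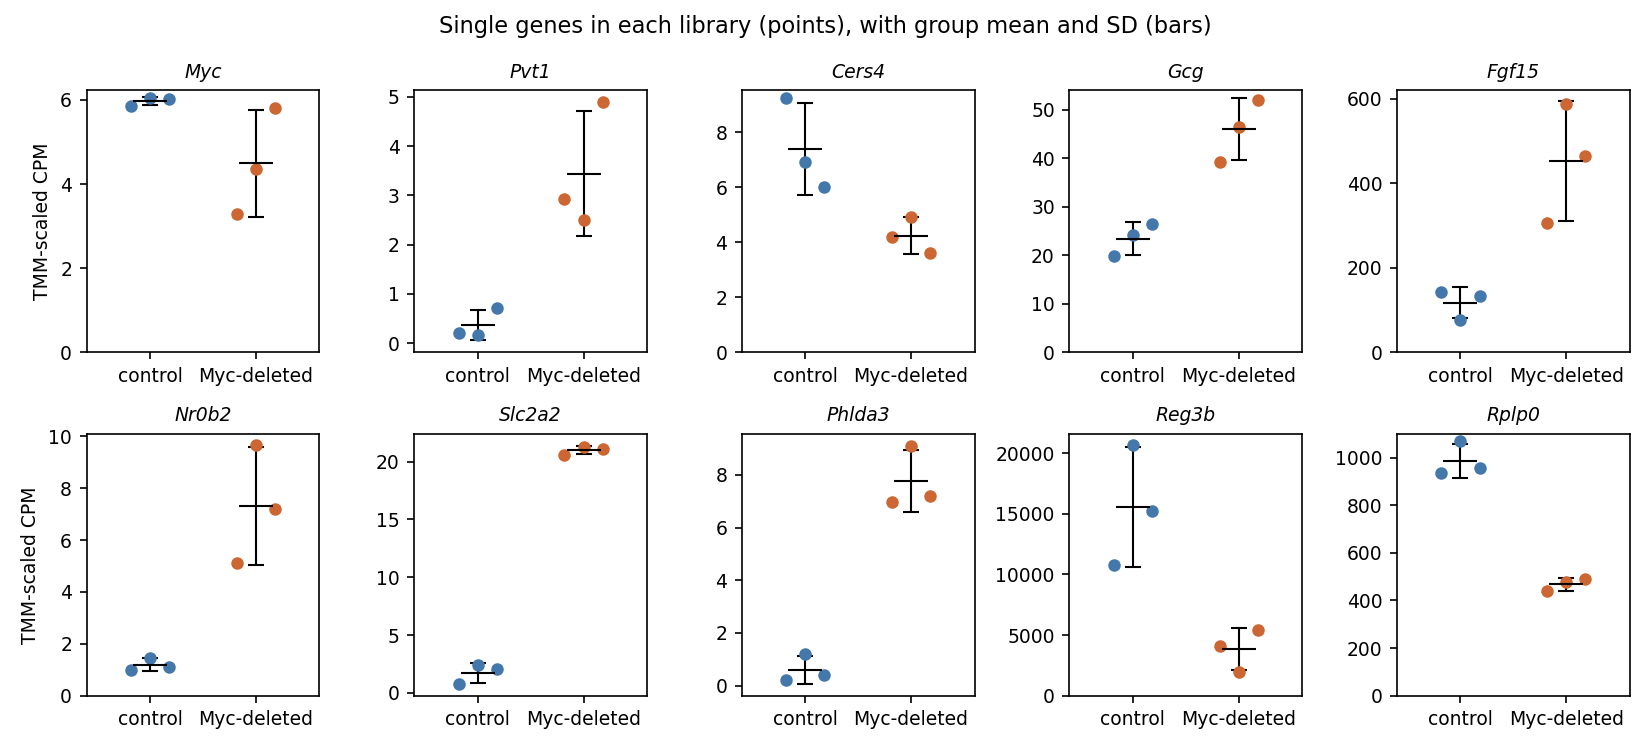
TMM-scaled CPM of 10 genes in each library (points), with group mean and SD (bars), 3 libraries per group. Fgf15, Nr0b2, Gcg, Slc2a2, Phlda3 and Pvt1 lay higher and Reg3b and Rplp0 lower in the Myc-deleted mice, while Myc and Cers4 did not pass the test.

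Of 38 ceramide and sphingolipid metabolism genes, 6 rose and 3 fell (6 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.409). For ceramide and sphingolipid metabolism, risers numbered 3 without control library 2 or Myc-deleted library 2, and fallers numbered 1 without control library 1 or 2 or Myc-deleted library 2. Cers4, a ceramide synthase gene (chromosome 8, 4493026 to 4531680), stood at 7.39 ± 1.66 CPM in the controls and 4.24 ± 0.663 CPM in the Myc-deleted mice. Every Myc-deleted library lay below every control, where 27.8% of all tested genes had groups that did not overlap. The difference in Cers4 did not pass (-0.80 ± 0.22, adjusted p = 0.0530). It passed with upper-quartile scaling (adjusted p = 0.0446) and without a filter on low counts (0.0204). Cers4 passed in no leave-one-out run (adjusted p = 0.0537 to 0.172). With RLE scaling, DESeq2, limma voom, the replicate number as a block or glmTreat it did not pass either. Asah2, the neutral ceramidase (1.14 ± 0.15, adjusted p = 0.00193), Cers2, a synthase of very-long-chain ceramides (0.46 ± 0.07, adjusted p = 0.00359), and Enpp7, the alkaline sphingomyelinase (1.57 ± 0.26, adjusted p = 0.00578), rose. Acer1, an alkaline ceramidase, fell (-1.15 ± 0.17, adjusted p = 0.00402). Smpd3, a neutral sphingomyelinase, rose (0.37 ± 0.08, adjusted p = 0.0200), with an adjusted p of 0.0638 and 0.117 without control library 1 or 2 and 0.0768 and 0.0647 without Myc-deleted library 2 or 3. Sptlc2, a subunit of the enzyme that starts ceramide synthesis, did not pass (-0.07 ± 0.09, adjusted p = 0.674), and its fold change was -0.13 without control library 1, -0.03 without control library 3, -0.02 without Myc-deleted library 2 and -0.14 without Myc-deleted library 3.

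Of 35 lipid absorption and chylomicron assembly genes, 5 rose (9 higher adjusted over the list alone; camera adjusted p = 2.31e-05, and adjusted p = 0.493 with an estimated correlation), among them Apoc2 (1.58 ± 0.30) and Fabp2, a fatty acid binding protein (0.90 ± 0.18). For lipid absorption and chylomicron assembly, risers numbered 0 without control library 2, 2 without Myc-deleted library 2 and 3 without Myc-deleted library 3. Without control library 2 the adjusted p was 0.0670 for Apoc2 and 0.0693 for Fabp2. Of 38 fatty acid oxidation and Ppar target genes, 7 fell and 1 rose (4 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.326), with a median of -0.03, a mean of 0.04 and a test in the downward direction. Angptl4, an inhibitor of lipoprotein lipase, was the riser (0.90 ± 0.17). For fatty acid oxidation and Ppar targets, risers numbered 2 without control library 1 or 3 and 3 without Myc-deleted library 1, and fallers numbered 1 without control library 1 or 2, 3 without control library 3 or Myc-deleted library 2 or 3 and 4 without Myc-deleted library 1. Of 18 fatty acid synthesis genes, 4 fell and 1 rose (2 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.190), including Fads2 (-0.59 ± 0.10) and the fatty acid synthase gene Fasn (-0.39 ± 0.07). For fatty acid synthesis, risers numbered 0 without control library 2 or 3 or Myc-deleted library 2 and 2 without Myc-deleted library 1, and fallers numbered 2 in each leave-one-out run. Of 26 cholesterol synthesis genes, 1 fell (3 lower adjusted over the list alone; camera adjusted p = 0.00579, and adjusted p = 0.555 with an estimated correlation), with a median of -0.20. For cholesterol synthesis, fallers numbered 0 without control library 2 or Myc-deleted library 2 or 3 and 4 without Myc-deleted library 1, and the camera adjusted p was 0.0513 without Myc-deleted library 2.

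Of 36 xenobiotic metabolism genes, 12 rose and 6 fell (18 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.0207, and adjusted p = 0.617 with an estimated correlation). For xenobiotic metabolism, risers numbered 7 without control library 2, and the camera adjusted p was 0.105 without Myc-deleted library 2. The aldo-keto reductase gene Akr1b8 rose (2.38 ± 0.26), and the glucuronosyltransferase gene Ugt2b5 (-2.17 ± 0.18) and the cytochrome gene Cyp3a25 (-1.46 ± 0.19) fell. Mthfd1, an enzyme of folate metabolism, fell (-1.27 ± 0.11, adjusted p = 0.000440) among 21 serine, one-carbon and polyamine metabolism genes, of which 1 rose and 2 fell (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.162). For serine, one-carbon and polyamine metabolism, fallers numbered 1 without control library 1 or 3 or Myc-deleted library 1 or 3. Of 24 purine and pyrimidine synthesis genes, 1 rose (Adss, 0.53 ± 0.09) and 1 fell (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0954). For purine and pyrimidine synthesis, fallers numbered 0 without control library 2 or 3 or Myc-deleted library 1, 2 or 3. Of 25 amino acid transport and Atf4 target genes, 3 rose (4 higher adjusted over the list alone; camera adjusted p = 0.0461, and adjusted p = 0.609 with an estimated correlation), led by the stress-response gene Trib3 (0.95 ± 0.14). For amino acid transport and Atf4 targets, risers numbered 1 without control library 1 or 2 or Myc-deleted library 3, fallers numbered 1 without Myc-deleted library 3, and the camera adjusted p was 0.208 without control library 1 or Myc-deleted library 3. Of 21 glycolysis genes, the hexokinase gene Hk1 rose (0.62 ± 0.10) and 1 fell (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.252). For glycolysis, risers numbered 2 without Myc-deleted library 2, and fallers numbered 0 without control library 1, 2 or 3 or Myc-deleted library 1 or 2. Of 14 gluconeogenesis and fructose metabolism genes, Slc2a2 rose and 1 fell (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.205). For gluconeogenesis and fructose metabolism, fallers numbered 0 without control library 2 or 3 or Myc-deleted library 3.

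Of 87 nuclear genes of the mitochondrial respiratory chain, 8 fell (19 lower adjusted over the list alone; camera adjusted p = 2.58e-05, and adjusted p = 0.617 with an estimated correlation), Cox7a2l (-0.62 ± 0.10) and Uqcrfs1 (-0.36 ± 0.07) among them. For mitochondrial respiratory chain, fallers numbered 2 without control library 1, 2 or 3 or Myc-deleted library 2, 3 without Myc-deleted library 1 and 4 without Myc-deleted library 3. No gene passed among 13 mitochondrially encoded genes (camera adjusted p = 0.800), with a median of 0.04, a mean of 0.000427 and a test in the downward direction. For mitochondrially encoded genes, risers numbered 1 without Myc-deleted library 1. Of 78 mitochondrial ribosomal proteins, 1 fell (0 adjusted over the list alone; camera adjusted p = 0.205). For mitochondrial ribosomal proteins, fallers numbered 0 without control library 1 or 3 or Myc-deleted library 1 or 2. Of 17 circadian clock genes, the repressor gene Nfil3 fell (-1.40 ± 0.19) and 1 rose (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.256). For circadian clock, risers numbered 0 without control library 1 or 2 or Myc-deleted library 1, 3 without control library 3 and 2 without Myc-deleted library 3.

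Of 43 interferon response genes, 24 rose (32 higher adjusted over the list alone; camera adjusted p = 3.70e-23, and adjusted p = 0.449 with an estimated correlation), with a median of 1.19 (0.78 without Myc-deleted library 3). Oas3 (1.83 ± 0.24), Oas1g (1.51 ± 0.20), Rtp4 (1.67 ± 0.24) and Stat2 (0.95 ± 0.15), antiviral effectors and a transcription factor of the pathway, had the lowest p. The mean log2 CPM of the list was 4.63, 3.99 and 4.67 in control libraries 1 to 3 and 5.32, 5.24 and 6.32 in Myc-deleted libraries 1 to 3. For interferon response, risers numbered 8 without control library 2. Of 17 antimicrobial and mucosal defence genes, 5 fell and 2 rose (4 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0604). For antimicrobial and mucosal defence genes, risers numbered 1 without control library 1, 2 or 3 and 4 without Myc-deleted library 2. The C-type lectin gene Reg3b went from 15544 ± 4929.6 to 3817 ± 1725 CPM (-2.03 ± 0.34, adjusted p = 0.00693), Reg3a fell (-1.56 ± 0.15), Reg4 rose (1.80 ± 0.23) and Saa1, an acute-phase gene, went from 332 ± 172 to 41.5 ± 29.5 CPM. No gene passed among 10 genes of antigen presentation by MHC class II (camera adjusted p = 0.540), 19 T and NK cell markers (camera adjusted p = 0.256) or 16 B and plasma cell markers (camera adjusted p = 0.998, median -0.05, test in the upward direction). For T and NK cell markers, fallers numbered 1 without control library 2. Of 16 myeloid and mast cell markers, the integrin gene Itgam fell (-1.55 ± 0.15, adjusted p = 0.000693; 1 lower adjusted over the list alone; camera adjusted p = 0.0207, and adjusted p = 0.449 with an estimated correlation). For myeloid and mast cell markers, the camera adjusted p was 0.0539 without control library 1 and 0.0729 without Myc-deleted library 2.

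Of 12 fibroblast markers, 2 rose, Fbln1 (1.74 ± 0.20) and Pdgfrb (1.33 ± 0.17) (2 higher adjusted over the list alone; camera adjusted p = 0.0207, and adjusted p = 0.493 with an estimated correlation). For fibroblast markers, the camera adjusted p was 0.0871 without control library 3 and 0.0924 without Myc-deleted library 1. No smooth muscle marker of 12 passed (camera adjusted p = 0.0757), and their mean log2 CPM was 3.87 in control library 2 and 2.24 to 2.70 in the others. For smooth muscle markers, fallers numbered 2 without control library 3. In control library 2, Myh11, a smooth muscle myosin, stood at 25.8 CPM, against 2.23 to 5.01 CPM in the other 5 libraries. Its log2 fold change was -1.83 ± 0.63, adjusted p = 0.119, and -0.53 without control library 2, and it passed without a filter on low counts (adjusted p = 0.00890). That library also had the lowest interferon level and a Reg3b level of 20640 CPM. No gene passed among 10 endothelial markers (camera adjusted p = 0.998, median -0.02, mean 0.000229, test in the downward direction) or 22 immediate early genes (camera adjusted p = 0.182). For immediate early genes, risers numbered 1 without control library 3 or Myc-deleted library 2 or 3. Over the 12 lists without a gene called by edgeR, 33 of 198 genes had an unadjusted p under 0.05, DESeq2 called 6 of them and limma voom 0. Adjusted over the list alone, these 12 lists also held 0 called genes. Of 9 hepatocyte markers, 3 fell (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.252), with a median of 0.23, a mean of -0.46 and a test in the downward direction. For hepatocyte markers, fallers numbered 1 without control library 1 or Myc-deleted library 2 or 3 and 0 without control library 2 or 3. Alb was 1 of them (-2.15 ± 0.52, adjusted p = 0.0326; 1 count in Myc-deleted library 2), with an adjusted p of 0.0514, 0.130 and 0.0903 without control library 1, 2 or 3 and 0.0591 and 0.0661 without Myc-deleted library 2 or 3, and of 0.0583 with the replicate number as a block. Lists with under 5 tested genes had no set test. The lipid droplet gene Cidec rose (0.51 ± 0.10) among 4 adipocyte markers (1 higher adjusted over the list alone). Cela1, an elastase gene, rose (1.10 ± 0.18) and 1 other fell among 4 pancreatic acinar markers (1 higher and 1 lower adjusted over the list alone). For pancreatic acinar markers, fallers numbered 0 without control library 1, 2 or 3 or Myc-deleted library 2 or 3. Of 4 erythrocyte genes, 2 fell (3 lower adjusted over the list alone). For erythrocyte genes, fallers numbered 0 without control library 2 or Myc-deleted library 2 and 1 without control library 3 or Myc-deleted library 3. Of 2 enteric neuron and glia markers, 1 fell (1 higher and 1 lower adjusted over the list alone). For enteric neuron and glia markers, fallers numbered 0 without control library 1, 2 or 3 or Myc-deleted library 2.

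In total 1011 genes passed, 2821 had an unadjusted p under 0.05, and 3533 genes (27.8%, where chance gives 10%) had groups that did not overlap. Of the 1011, 421 kept their call in every leave-one-out run, and the number called was 462 without control library 2, 646 without control library 1 and 639 without Myc-deleted library 2. Camera with the preset correlation called 19 of 44 lists, but it also called 12 to 20 in the other splits of the 6 libraries, and with an estimated correlation it called 0 (4 at an unadjusted p under 0.05, and fry called 8). Each other split has libraries of both groups on each side, so it keeps part of the group difference and is not a clean null.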

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

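The scaling without ribosomal protein and interferon genes was chosen after the result was seen. No called gene changed sign under any alternative run. The 1011 calls numbered 1009 with RLE scaling, 1040 with upper-quartile scaling (923 shared), 1037 with DESeq2 (876 shared), 1004 with limma voom (967 shared), 1273 without a filter and 994 with the added scaling (985 shared). Upper-quartile scaling moved the share of lower genes from 46.9% to 56.8% and turned the sign of Ldha (-0.0286); the cause was not tested. Against a 1.2-fold change 408 genes passed (230 higher, 178 lower), a stricter null, and 1572 passed at an adjusted p of 0.1 (824 higher, 748 lower), a looser threshold. Leaving out 1 library gave 462 to 950 genes, 229 to 503 higher and 233 to 447 lower, with fewer samples; the lowest were without control library 2. Over these runs the log2 fold change was -0.0137 to 0.0294 for Ldha and -0.151 to 0.0412 for Fabp6. Of the 19 lists called by camera, 14 were kept on ranks, 4 with fry, which called 8, and 0 with an estimated correlation, which called 0 (4 at an unadjusted p under 0.05). The 4 kept with fry were the ribosomal protein, p53, ileal and colonic lists. Fry also called the Myc network, the serine, one-carbon and polyamine list, the bile acid and Fxr list and the hepatocyte markers.

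With the replicate number as a replicate block 980 genes passed, 855 of them shared with the 1011. Deviations from the group mean correlated by 0.0261, 0.0524 and 0.0189 between libraries of the same number. Between libraries of different numbers the correlations were lower, from -0.0359 to 0.00983. The deviations cancel out within a group, so these lower values largely follow from the positive ones and are no separate evidence. Some pairing cannot be excluded. The labels name no batch, litter or day, and for that reason the main fit did not treat the numbers as pairs.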

Other observations

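The count of genes under other splits, the cell cycle and ileal comparisons, the question of the recombinase and the neighbourhood of Myc were tests chosen after the result was seen. Near Myc on chromosome 15, Gsdmc4 (-2.77), Gsdmc3 (-2.83), Gsdmc2 (-2.52) and Gsdmcl2 (-2.59), adjacent members of the gasdermin C family (63824346 to 63912297), fell and Pvt1 rose. These 5 genes are among 11 tested within 2.5 Mb on each side of Myc, and the 4 gasdermin genes are adjacent paralogs. Of the other 6, edgeR called 0 (0 at an unadjusted p under 0.05), limma voom 0 and DESeq2 0. At the share called elsewhere, 7.92%, that many genes hold no call with a probability of 0.610, so whether changes are concentrated around the deleted locus stays open.

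The real split gave 1011 genes, and it was the 1 of 10 splits with a result as large, the highest other giving 0 by edgeR (224 to 512 at an unadjusted p under 0.05, and 0 by limma voom). For the lists, 2 of 10 splits gave as many as the real 19, the highest other giving 20. With 10 splits no share under 0.05 can be had. The other splits mix the groups on each side, which keeps part of the group difference and widens the spread within a side. Their counts are therefore not those of libraries without a difference.

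Ribosomal protein mRNAs had a median log2 fold change of -0.63. Other genes matched on length, GC content and level had a median of 0.0274 (281 genes, quartiles -0.13 to 0.14), which argues against a bias by these features as measured. Length was that of all annotated exons of a gene together, with a median of 1805.5 bases against 2171 in the matched genes. A bias by the length of the mRNA itself was not tested. Processed pseudogenes did not gain the reads, as their change was -0.308% of the CPM lost. The cell cycle list stood above the ribosomal protein list in its change, by 0.548 in mean log2 CPM, which argues against a lower share of proliferating cells as the whole cause. The deletion of Myc, named by the design, may account for the pattern as a hypothesis, and Cre activity and litter were not tested for it.

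Lct, Slc2a2 and Gata4 were higher and Car4, Saa1 and Slc40a1 lower, as genes that differ along the intestine. Slc40a1, like Lct and Gata4, is on the proximal small intestine list, so its fall runs against their rise. A more proximal piece in the Myc-deleted mice would lower ileal genes. The ileal list was instead higher by 0.396 in mean log2 CPM, and by 0.28 without the 10 of 18 genes that another list holds. Fabp6 (-0.15 to 0.04), Slc10a2 (0.07 to 0.20), Slc51a (-0.22 to -0.09) and Slc51b (-0.27 to -0.16) passed in no leave-one-out run. The second value leaves these ileal genes out. The proximal small intestine list differed by 0.395, and by -0.257 without shared genes. The list levels therefore do not exclude a more proximal piece. Less colonic tissue is argued against by a median log2 ratio of 0.0104 over 6 colonic genes, with Aqp8 at 0 counts in every library and Car1 at 0.212 CPM in the controls. Slc26a3 (141 CPM) is also expressed in small intestine and weighs less. An effect of the deletion, a more proximal piece and other differences in sampling stay open.

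The p53 targets were higher by a median of 0.25, while 120 genes matched on length, GC content and level had a median of 0.0142. This argues against a bias by these features, with length again that of all annotated exons. The list differed by 0.439 in mean log2 CPM between the groups, and loss of Myc and activity of a Cre recombinase cannot be told apart for it. The labels name no library with a recombinase and an intact Myc gene, and do not say whether the controls carry a recombinase. The same limit holds for every other gene and list compared here.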
